A study of Mus musculus with 25 samples.

How the data were processed

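The data were bulk messenger RNA sequencing libraries (100 bp paired reads) of neutrophils taken from mouse bone marrow at the interface of 68% and 78% Percoll, from female mice aged 6 to 13 weeks, per the labels' protocols. The age of each mouse was not used here. The authors deposited a table of estimated counts per gene, 35741 gene symbols by 25 libraries, made with Salmon 0.14.1 on GRCm38.p6 per the submitters' processing notes, which also name DESeq2. How transcripts were summed to genes is not stated. The values are expected counts, not scaled to depth or gene length, and were rounded to whole numbers. Totals ran from 21598063 to 23187557 estimated counts per library. Every column was matched to a sample. Of the symbols tested, 92.6% matched a RefSeq gene of the same build, which supplied coordinates.

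Groups were taken from the genotype labels. The library whose labels conflict was left out of every comparison, and Casp8 cKO Ptpn6 cKO, with 1 library, was described without a test. The other 23 libraries in 9 groups were fitted together with edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr (minimum count 10, minimum total 15) and the quasi-likelihood F test, leaving 14 residual degrees of freedom and 16206 genes. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. There were 14 comparisons. CPM of named genes used effective library sizes over all libraries. The replicate numbers were checked for pairing by correlating deviations from group means. No comparison with 3 shared numbers had every correlation above 0.1, so the samples were not treated as paired. Among those with 2 shared numbers, Ripk3 KO Mlkl KO against wild type (0.121 and 0.179) and Casp8 deletion in Mlkl KO Ptpn6 cKO (0.32) did. In the latter each group had 2 libraries, so both numbers give the same correlation by construction and count as 1 value.

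Gene lists (16 pathway lists and 11 lists of markers of other cell types) were fixed before the data were examined, as were the comparisons, the tests and the rule for naming genes. Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with adjustment over the 27 lists of a comparison, and checked with an estimated correlation and with fry. Some lists share members with each other, and neutrophils themselves express many pathway members.

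The naming rule took the targeted genes in every library and, per comparison, the 8 largest rises and 8 largest falls among called genes with at least 5 CPM in the higher group and no overlap between groups. It took 10 and 10 with the same sign in each background for the averaged effect, and the 6 smallest p values for the F test and the interaction. It also took up to 4 members that moved with each called list, and called members that went against it. Predicted genes and receptor segments were counted but not named. The single-gene results of 1 further list member are not reported here. For length, members are spelled out for some of the lists under a camera adjusted p of 1e-04, a limit set after the values were seen, while the alternatives were run on the members of all 161 list results. Genes of the chromosomal windows, Eif3j1, and per-library values of chosen genes were picked after their values were seen.

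Alternatives were DESeq2's size factors in edgeR, no filter on low counts, DESeq2 1.42.0 tests, a fit of only the libraries compared, a replicate block, and leaving out each library in turn. Chosen after seeing the data were a covariate of mean B cell marker level, and the source of the Ptpn6 gene sets. Where leaving out a library left a group with 1, that library was assumed to vary like the other groups.

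The pipeline was first tested on simulated data drawn from the real means, dispersions and library sizes, with 200 genes changed 2-fold or 4-fold. For Ptpn6 deletion in Ripk3 KO it recovered 45 of 100 genes changed 2-fold and 77 of 100 changed 4-fold, among 16166 genes, with 7 others called. Each gene was drawn independently, so the simulated libraries held no shifts shared by many genes. The Casp8 cKO Ptpn6 cKO library was scaled together with the libraries it was compared with, so its CPM values there differ slightly from those scaled over all libraries, and it was set against 10000 random lists matched on expression. Figures were drawn with matplotlib 3.10.9.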

Results

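Neutrophils from the bone marrow of female C57BL/6J mice were profiled by bulk messenger RNA sequencing to ask how the phosphatase Ptpn6 (SHP-1) restrains inflammation and which parts depend on caspase-8 or on Ripk3 and Mlkl, the kinase and the effector of necroptosis. The mice carried whole-body knockouts (KO) of Ripk3, Mlkl or both, with or without conditional deletion in neutrophils (cKO) of Ptpn6 and of Casp8. There were 25 libraries. Wild type, Ripk3 KO, Ripk3 KO Ptpn6 cKO, Mlkl KO and Ripk3 KO Mlkl KO Ptpn6 cKO had 3 libraries each. Mlkl KO Ptpn6 cKO, Ripk3 KO Mlkl KO, Mlkl KO Casp8 cKO Ptpn6 cKO and Ripk3 KO Mlkl KO Casp8 cKO Ptpn6 cKO had 2 each. Casp8 cKO Ptpn6 cKO had 1, and 1 library with conflicting labels was placed in no group. Totals ran from 21598063 to 23187557 estimated counts per library.

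Ptpn6 and Ripk3 followed the genotype labels in every assigned library. Ptpn6 stood at 596 ± 22.2 CPM (counts scaled to library size, ± SD, n = 3) in wild type and at 228 ± 59.0 (n = 3) in Ripk3 KO Ptpn6 cKO. It was at 188 ± 8.20 (n = 2) in Mlkl KO Ptpn6 cKO and at 293 ± 32.6 (n = 3) in Ripk3 KO Mlkl KO Ptpn6 cKO. Ripk3 had 720 counts over the wild-type libraries, and the 5 groups labelled as lacking it had 1, 7, 2, 3 and 1 counts in all. Ripk3 also fell in Mlkl KO (log2 change -1.52, SE 0.32, edgeR adjusted p = 0.0229), at 3.36 ± 1.24 CPM against 9.65 ± 0.961 in wild type (n = 3 each). That call was lost in 5 of 6 fits that left out 1 library (log2 change -1.60 to -1.35, edgeR adjusted p = 0.0718 to 0.167) and with a B cell marker covariate (log2 change -1.06, edgeR adjusted p = 0.0788). Ripk3 stood at 3.72 ± 1.14 CPM in Mlkl KO Ptpn6 cKO and 4.20 ± 1.45 in Mlkl KO Casp8 cKO Ptpn6 cKO (n = 2 each). It was at 5.51 in the Casp8 cKO Ptpn6 cKO library, which has Mlkl intact. Mlkl was at 0.715 ± 0.187 CPM in Mlkl KO, 1.61 ± 0.223 in Ripk3 KO and 4.22 ± 0.680 in wild type (n = 3 each). Single Mlkl KO libraries of all groups lay between 0.230 and 1.64 and the others between 1.40 and 4.86, so Mlkl overlapped. Casp8 was at 19.6 ± 2.98 and 19.9 ± 5.10 CPM in the replicated Casp8 cKO groups (n = 2 each) and 35.1 ± 2.47 in wild type (n = 3). Single libraries overlapped here too, from 16.3 to 23.5 with Casp8 deletion and from 21.3 to 37.9 without. The counts are gene totals and do not separate the deleted part of a gene from the rest.

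**Figure D1:**
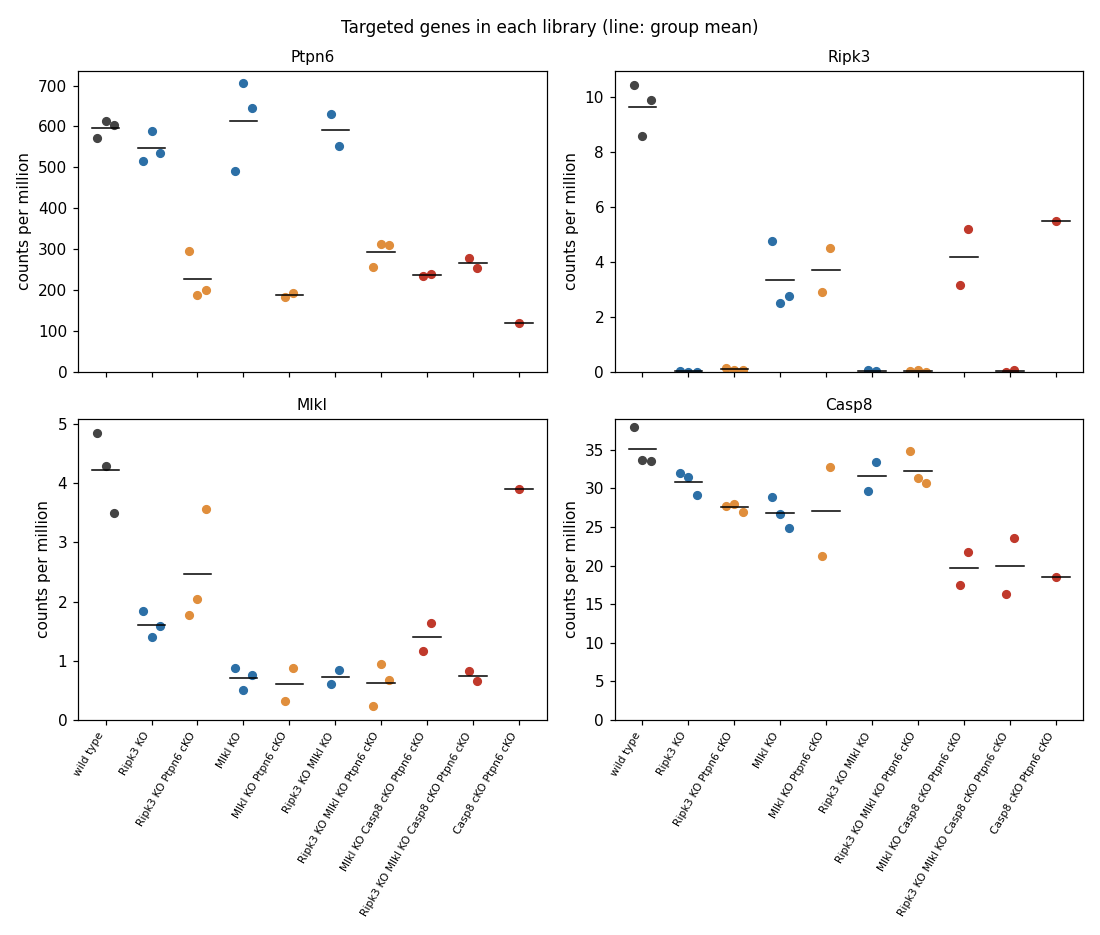
CPM of the targeted genes in each assigned library (points), by group, with group means as lines. Ptpn6 lay at 596 in wild type on average and lower in each group with Ptpn6 deletion, Ripk3 lay near 0 in each group labelled Ripk3 KO, and the axes start at 0.

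In neutrophils that lacked Ripk3, Ap1s1 lay higher and Sh2b2 lower with Ptpn6 deletion. No library combined Cre-mediated deletion of another gene with intact Ptpn6. In any background, a response to the loss of Ptpn6 therefore cannot be told apart from DNA carried with the deletion. Ap1s1, a subunit of the AP-1 clathrin adaptor, rose 7.42-fold, from 11.4 ± 0.818 to 84.7 ± 22.4 CPM (n = 3 each, log2 change 2.89, SE 0.24, edgeR adjusted p = 4.62e-06). Sh2b2, an adaptor protein of tyrosine kinase signalling, fell by 1.86 on the log2 scale (SE 0.23, edgeR adjusted p = 0.00121), and Ptpn6 itself fell by 1.26 (SE 0.16, edgeR adjusted p = 0.00121). These were the 3 genes called among 16206 tested by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with 892 at an unadjusted p under 0.05. Without Ripk3 KO Ptpn6 cKO replicate 1 there were 156, DESeq2 called 34, and a fit of only these libraries called 1. Genes of glycolysis and hypoxia lay higher as a list (20 of 22 above 0, median log2 change 0.22, camera adjusted p = 3.18e-06), and the adjusted p with an estimated correlation was 0.809. None of its 22 members passed over all genes, and 2 passed when adjusted over the list alone. B cell markers lay lower in all 12 in the same comparison (camera adjusted p = 0.00146, adjusted p = 0.812 with an estimated correlation).

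The same deletion in Mlkl KO neutrophils moved 160 genes up and 84 down past the threshold, and the count was 2 without Mlkl KO Ptpn6 cKO replicate 2. Lipg, which encodes endothelial lipase, went from 3.44 ± 0.932 to 174 ± 152 CPM, and Nos2, the inducible nitric oxide synthase, from 0.200 ± 0.123 to 21.5 ± 25.9 (n = 3 and n = 2). Their edgeR adjusted p values were 0.00956 and 0.0236, and the fitted fold of Nos2 rests on a control level close to 0. Ap1s1 rose by 3.50 (SE 0.26), the chemokine-like gene Prok2 by 2.88 (SE 0.57) and the secreted-protein kinase Fam20c by 3.77 (SE 0.60) on the log2 scale. Among the falls were the BH3-only gene Pmaip1, which fell by 4.01 (SE 0.96, edgeR adjusted p = 0.0444), and the integrin Itgax, which fell by 2.21 (SE 0.54, edgeR adjusted p = 0.0452). Ptpn6 fell by 1.71 (SE 0.18). For all 244 called genes the values of the groups did not overlap. The same held for every gene called in the other comparisons of 2 groups, so it adds no support to the count.

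Interferon-response genes moved together in this background. All 28 lay higher (median log2 change 1.08, camera adjusted p = 1.02e-24, adjusted p = 0.366 with an estimated correlation), 7 passed over all genes and 24 when adjusted over the list alone. Zbp1, a nucleic-acid sensor, rose by 1.84 (SE 0.35) and Stat2 by 0.92 (SE 0.17), with edgeR adjusted p values of 0.0253 and 0.0236. Specific-granule genes lay higher in 16 of 16 (median log2 change 0.76, camera adjusted p = 3.33e-09, adjusted p = 0.451 with an estimated correlation). None passed over all genes, and 9 did when adjusted over the list alone. B cell markers lay lower in all 12 (camera adjusted p = 2.52e-05, adjusted p = 0.5002 with an estimated correlation), and their mean level was 5.21 ± 0.03 log2 units in Mlkl KO Ptpn6 cKO (n = 2) and 6.07 ± 0.29 in Mlkl KO (n = 3). The count of 244 was 31, 4 and 6 without Mlkl KO replicate 1, replicate 2 and replicate 3, and 7 with a B cell marker score as a covariate.

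**Figure D2:**
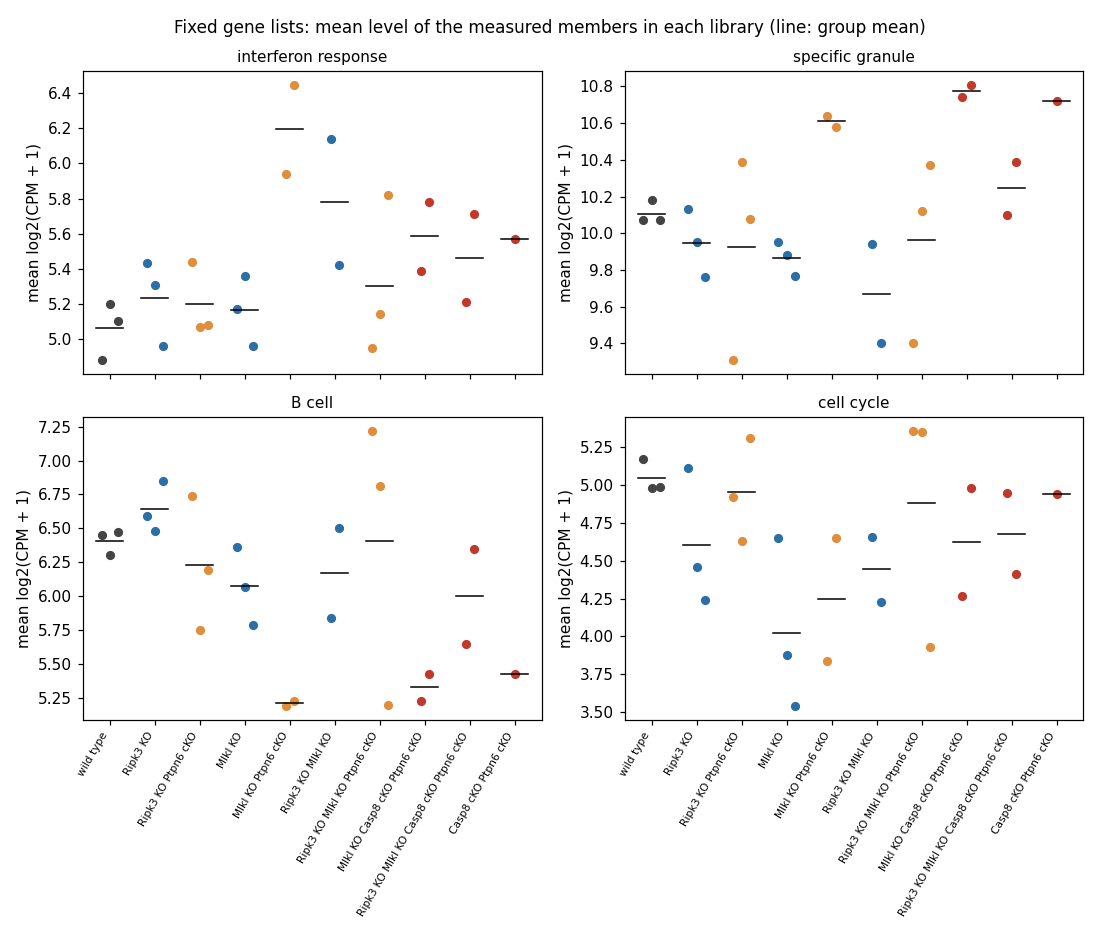
Mean log2(CPM + 1) of the measured members of 4 fixed gene lists in each assigned library (points), by group, with group means as lines. Interferon-response genes averaged 6.20 in Mlkl KO Ptpn6 cKO and 5.16 in Mlkl KO, while B cell markers averaged 5.21 and 6.07.

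Without both Ripk3 and Mlkl, Ap1s1 lay 9.68-fold higher with Ptpn6 deletion, at 87.7 ± 20.2 (n = 3) against 9.05 ± 1.26 (n = 2) CPM (log2 change 3.28, SE 0.29, edgeR adjusted p = 1.30e-05). This was the 1 gene called, with 830 at an unadjusted p under 0.05, and there were 18 without Ripk3 KO Mlkl KO replicate 3. DESeq2 called 4. Ptpn6 itself had a log2 change of -1.01 (SE 0.17, edgeR adjusted p = 0.0838) and did not pass. Interferon-response genes lay lower here, with 2 of 28 above 0 (median log2 change -0.48, camera adjusted p = 1.84e-10, adjusted p = 0.655 with an estimated correlation), and none passed over all genes. By library, their mean was 6.14 (replicate 2) and 5.42 (replicate 3) log2 units in Ripk3 KO Mlkl KO. It was 4.95, 5.14 and 5.82 with Ptpn6 deletion, so the groups overlapped. Among the assigned libraries the difference leaned on Ripk3 KO Mlkl KO replicate 2. The library with conflicting labels, left out here, averaged 5.80. Erythroid markers lay lower in all 14 (camera adjusted p = 2.10e-09, adjusted p = 0.655 with an estimated correlation).

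Averaged over the 3 backgrounds, 122 genes lay higher and 129 lower with Ptpn6 deletion. Ap1s1 rose by 3.22 (SE 0.15, edgeR adjusted p = 3.27e-10), Lipg by 3.46 (SE 0.49), Prok2 by 2.13 (SE 0.33) and Wfdc17, a gene of the whey acidic protein family, by 2.08 (SE 0.35) on the log2 scale. Sh2b2 fell to 0.354 of its control level, the ficolin Fcna fell by 1.57 on the log2 scale (SE 0.34), and the haptoglobin-haemoglobin receptor Cd163 fell by 1.17 (SE 0.29). Each of these had the same sign in the 3 backgrounds, which the rule for naming them required. Whether the falls of Fcna and Cd163 came from neutrophils or from other cells of the preparation was not tested. Across the 13 assigned libraries with Ptpn6 deletion Ap1s1 lay between 65.4 and 157 CPM, against 8.16 to 14.1 in the 11 assigned libraries without it. Sh2b2 lay between 6.68 and 13.7 with deletion and between 17.7 and 38.8 without. The count of 251 was 22 in a fit of only the libraries compared, 7 without Mlkl KO Ptpn6 cKO replicate 2, 444 without Mlkl KO Ptpn6 cKO replicate 1 and 1037 without Ripk3 KO Ptpn6 cKO replicate 1. It was 110 and 96 without Ripk3 KO Ptpn6 cKO replicate 2 and replicate 3, 114 and 93 without Ripk3 KO replicate 2 and replicate 3, 128 and 121 without Mlkl KO replicate 2 and replicate 3, and 82 without Ripk3 KO Mlkl KO replicate 3.

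**Figure D3:**
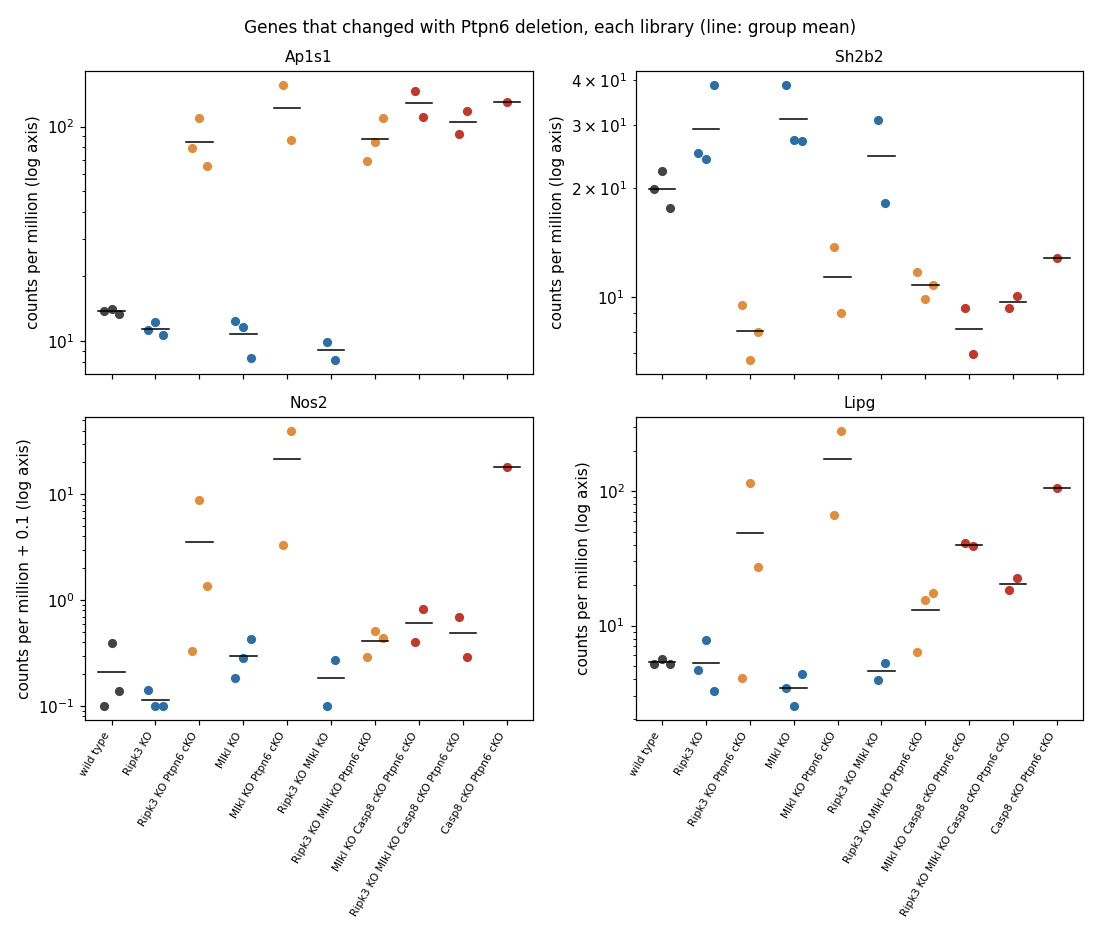
CPM on log axes (0.1 added for Nos2) in each assigned library (points), by group, with group means as lines. Ap1s1 lay between 65.4 and 157 in the 13 libraries with Ptpn6 deletion and between 8.16 and 14.1 in the 11 others.

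A test of whether the effect of Ptpn6 deletion differed among the 3 backgrounds called 0 genes by edgeR's F test, with 1053 at an unadjusted p under 0.05, and 31 by DESeq2's likelihood-ratio test. There were 34 without Ripk3 KO Mlkl KO Ptpn6 cKO replicate 3 and 9 without Ripk3 KO Mlkl KO replicate 3. The smallest p belonged to Sncaip (edgeR adjusted p = 0.204), which encodes synphilin-1, followed by Wdr7 (edgeR adjusted p = 0.429). Both lie on chromosome 18. The genes called in Mlkl KO, without Ptpn6, Ap1s1 and Sh2b2, were followed in libraries they did not come from, a source of genes chosen after the data were seen because the planned source held 3. In Ripk3 KO, 141 of the 159 higher genes had the same sign (median log2 change 0.36, camera adjusted p = 2.12e-41), as did 74 of the 82 lower genes (median -0.37, camera adjusted p = 3.36e-20). The adjusted p was 0.0622 for each with an estimated correlation. In Ripk3 KO Mlkl KO, 103 of 159 and 65 of 82 had the same sign (camera adjusted p = 0.0538 and 2.69e-05, with adjusted p = 0.711 and 0.317 with an estimated correlation).

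Against wild type, the knockout lines without any conditional deletion shared a set of changes. Ugt1a6b, a glucuronosyltransferase gene, rose by 2.99 in Ripk3 KO, 3.45 in Mlkl KO and 2.93 in Ripk3 KO Mlkl KO on the log2 scale (edgeR adjusted p = 9.87e-06, 2.35e-06 and 2.17e-05). Hebp1, a haem-binding protein gene, rose 4.89-fold, 4.69-fold and 5.69-fold, and Klra17, a gene of the Ly49 receptor family, rose 3.27-fold, 4.23-fold and 4.37-fold. The C-type lectin receptor Clec1b fell, with log2 changes of -3.51, -2.83 and -3.19 (SE 0.41, 0.40 and 0.48), and the receptor gene Klrc1 fell to 0.249, 0.144 and 0.252 of the wild-type level. Eif3j2 rose while its near-identical copy Eif3j1 stood at 5.45, 7.91 and 0.0930 CPM against 15.0 in wild type, so reads may have been divided between them. Ugt1a6b and the Klr and Clec genes also belong to families of similar sequence, and their values are uncertain for the same reason. Arl4c, a gene of none of these families, lies close to Ugt1a6b on chromosome 1 and was also called higher in each line. Its log2 change was 1.56 in Ripk3 KO and 1.72 in Mlkl KO (edgeR adjusted p = 6.90e-05 and 2.27e-05). A difference local to chromosome 1 was not tested, so shared reads are not settled as the cause for Ugt1a6b.

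In all, 37 genes were called in Ripk3 KO (20 higher), 188 in Mlkl KO (145 higher) and 169 in Ripk3 KO Mlkl KO (127 higher) by edgeR, and 32 were called in the 3 comparisons together. Of these, 17 lay on chromosome 6 and 11 lay within 10 Mb of Ptpn6. The comparisons use the same wild-type libraries, which makes shared calls more frequent. In 20 simulations without any effect the highest number shared by a pair was 1. Each simulated comparison called at most 1 gene, so the simulations cannot say how many of the 32 come from the common wild-type libraries. The count for Ripk3 KO was 23 without wild type replicate 1 and 24 without wild type replicate 2. For Mlkl KO it was 38, 40 and 57 without wild type replicate 1, replicate 2 and replicate 3, and 589, 79 and 47 without Mlkl KO replicate 1, replicate 2 and replicate 3. For Ripk3 KO Mlkl KO it was 29, 44 and 41 without wild type replicate 1, replicate 2 and replicate 3, and 19 and 85 without Ripk3 KO Mlkl KO replicate 2 and replicate 3.

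**Figure D4:**
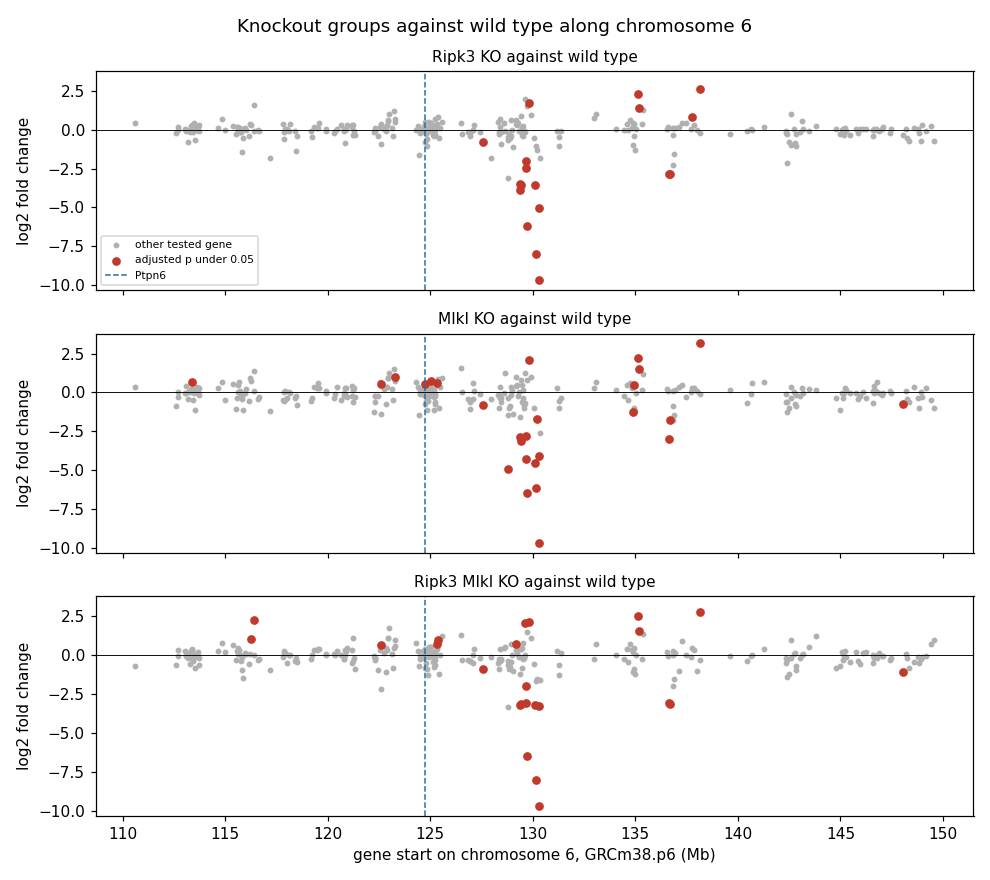
Log2 fold change of tested genes (points) against gene start in Mb on the distal part of chromosome 6, GRCm38.p6, for each knockout group against wild type, with called genes in red and Ptpn6 as a dashed line. Of the 196 genes tested within 10 Mb of Ptpn6, 12, 18 and 18 were called.

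In Mlkl KO against wild type, cell cycle genes lay lower in all 20 (median log2 change -1.06, camera adjusted p = 2.84e-10, adjusted p = 0.425 with an estimated correlation). Their mean level was 4.65, 3.88 and 3.54 log2 units in the Mlkl KO libraries and 5.17, 4.98 and 4.99 in wild type, so replicate 1 of Mlkl KO lay nearest to wild type. Azurophil granule genes lay lower in all 11 (camera adjusted p = 1.87e-05) and gelatinase granule genes higher in 16 of 17 (median 0.46, camera adjusted p = 1.31e-08), each with an adjusted p of 0.425 with an estimated correlation. Among the latter was Il1r2, the interleukin-1 decoy receptor, which rose by 1.04 (SE 0.21, edgeR adjusted p = 0.0213). Cd14, a co-receptor for lipopolysaccharide, rose 10.3-fold (edgeR adjusted p = 0.0163), from 9.13 ± 0.823 to 94.0 ± 66.6 CPM (n = 3 each), with the Mlkl KO libraries at 17.9, 142 and 122. Of the marker lists of other cells given next, basophil and mast cell passed camera's threshold and B cell did not. Basophil and mast cell markers averaged 5.82, 5.69 and 4.11 log2 units against 6.13, 6.02 and 6.11 in wild type (camera adjusted p = 0.00301, adjusted p = 0.451 with an estimated correlation). B cell markers averaged 6.36, 6.07 and 5.79 against 6.45, 6.30 and 6.47 (camera adjusted p = 0.143), in the same library order as the cell cycle genes. In Ripk3 KO Mlkl KO, interferon-response genes lay higher in all 28 (median 0.78, camera adjusted p = 2.24e-13, adjusted p = 0.418 with an estimated correlation), with none past the threshold over all genes and 19 when adjusted over the list alone. Basophil and mast cell markers lay lower in 8 of 9 there (camera adjusted p = 2.69e-08, adjusted p = 0.327 with an estimated correlation). Among them Gata2, a transcription factor of that lineage, fell by 1.91 (SE 0.41, edgeR adjusted p = 0.0299). Erythroid markers lay higher in all 14 (camera adjusted p = 0.000713, adjusted p = 0.602 with an estimated correlation).

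Deleting Casp8 together with Ptpn6 was compared with deleting Ptpn6 alone. In Mlkl KO no gene was called by edgeR, with 1515 at an unadjusted p under 0.05, and DESeq2 called 90. In Ripk3 KO Mlkl KO edgeR also called 0, with 750 at an unadjusted p under 0.05, and DESeq2 called 1. Without Mlkl KO Casp8 cKO Ptpn6 cKO replicate 2, or without Ripk3 KO Mlkl KO Casp8 cKO Ptpn6 cKO replicate 1, the respective count was 1. In simulated counts, 61 of 100 genes changed 4-fold and 29 of 100 changed 2-fold were recovered for the first comparison, and 71 and 42 of 100 for the other. The simulated genes varied independently, so these rates leave out shifts shared by many genes of a library. Interferon-response genes lay lower with Casp8 deletion in Mlkl KO, with none of 28 above 0 (median log2 change -0.65, camera adjusted p = 1.22e-12, adjusted p = 0.734 with an estimated correlation). The same libraries differed in erythroid markers, which averaged 3.89 and 5.55 log2 units with Casp8 deletion and 6.20 and 5.92 without (camera adjusted p = 3.30e-08, adjusted p = 0.734 with an estimated correlation). In Ripk3 KO Mlkl KO, azurophil granule genes lay higher in 10 of 11 (median 0.67, camera adjusted p = 1.28e-06, adjusted p = 0.375 with an estimated correlation), and T and NK cell markers lay lower in all 13 (camera adjusted p = 3.42e-06, adjusted p = 0.404 with an estimated correlation). B cell and erythroid markers also lay lower there (camera adjusted p = 0.00253 each, adjusted p = 0.512 with an estimated correlation).

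Whether the Casp8 effect depended on Ripk3 was tested as an interaction. Sncaip was the 1 gene called (log2 difference 6.31, SE 0.83, edgeR adjusted p = 0.00658), with 1505 at an unadjusted p under 0.05 and 10 called by DESeq2. Sncaip stood at 5.77 ± 2.74 CPM in Mlkl KO Ptpn6 cKO and 0.742 ± 0.161 with Casp8 deletion (n = 2 each). In the absence of Ripk3 it stood at 0.197 ± 0.00647 (n = 3) and 2.07 ± 2.22 (n = 2), the latter from libraries at 0.5 and 3.65. The call was lost without Mlkl KO Ptpn6 cKO replicate 2, without either Mlkl KO Casp8 cKO Ptpn6 cKO library (replicate 1 or replicate 2) and without Ripk3 KO Mlkl KO Casp8 cKO Ptpn6 cKO replicate 2, where 0 genes were called. In these 4 fits the log2 difference was 4.27 to 6.55 (SE 0.66 to 1.04, edgeR adjusted p = 0.0663 to 0.110). A fit of only the libraries compared lost the call too (edgeR adjusted p = 0.838), where the log2 difference was 6.32 and its SE 1.09. There were 2 without Ripk3 KO Mlkl KO Casp8 cKO Ptpn6 cKO replicate 1.

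Among neutrophils lacking Mlkl and Ptpn6, Ripk3 itself, Sncaip and B4galt6, a galactosyltransferase gene, lay lower in those without Ripk3. Sncaip and B4galt6 both lie on chromosome 18, and a difference local to that chromosome was not tested. Sncaip fell by 4.83 (SE 0.57, edgeR adjusted p = 0.000705) and B4galt6 fell by 1.40 (SE 0.22, edgeR adjusted p = 0.0283) on the log2 scale. These 3 were the genes called, with 4237 at an unadjusted p under 0.05. Without Ripk3 KO Mlkl KO Ptpn6 cKO replicate 3 there were 4861, without Mlkl KO Ptpn6 cKO replicate 1 there were 23, and DESeq2 called 1572, which held 2 of the 3. A replicate block gave 431, and a fit of only the libraries compared called 1 gene, none of these 3. B cell markers lay higher in all 12 (median log2 change 1.46, camera adjusted p = 7.79e-08) and interferon-response genes lay lower, with 1 of 28 above 0 (median -0.92, camera adjusted p = 2.64e-15). Both had an adjusted p of 0.322 with an estimated correlation. By library, the B cell mean was 7.22, 6.81 and 5.20 log2 units in Ripk3 KO Mlkl KO Ptpn6 cKO, against 5.19 and 5.23 in Mlkl KO Ptpn6 cKO, so replicate 3 did not carry the rise. The interferon mean was 4.95, 5.14 and 5.82, against 5.94 and 6.45.

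Loss of Mlkl in neutrophils lacking Ripk3 and Ptpn6 gave 0 genes by edgeR, with 482 at an unadjusted p under 0.05, and 1 by DESeq2. There was 1 without Ripk3 KO Ptpn6 cKO replicate 1 and 1 without Ripk3 KO Mlkl KO Ptpn6 cKO replicate 1. Azurophil granule genes lay lower, with 2 of 11 above 0 (median log2 change -0.70, camera adjusted p = 1.26e-08, adjusted p = 0.246 with an estimated correlation), while B cell markers lay higher in all 12 (camera adjusted p = 0.0328, adjusted p = 0.918 with an estimated correlation). With Casp8 also deleted, loss of Ripk3 in Mlkl KO called Ripk3 alone, with 1177 at an unadjusted p under 0.05 and 3 by DESeq2. There were 2 without Mlkl KO Casp8 cKO Ptpn6 cKO replicate 1 and 2 without Ripk3 KO Mlkl KO Casp8 cKO Ptpn6 cKO replicate 2. Specific-granule genes lay lower there in all 16 (median -0.42, camera adjusted p = 3.52e-06, adjusted p = 0.826 with an estimated correlation). B cell markers lay higher in all 12 of the same comparison (camera adjusted p = 3.05e-05, adjusted p = 0.826 with an estimated correlation), at 5.65 and 6.35 log2 units without Ripk3 and 5.23 and 5.43 with it.

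The Casp8 cKO Ptpn6 cKO library, the one labelled as inflamed, had no replicate, so its values describe that library. Nos2 stood at 16.4 CPM in it, against means of 0.474 in Mlkl KO Casp8 cKO Ptpn6 cKO and 0.360 in Ripk3 KO Mlkl KO Casp8 cKO Ptpn6 cKO. Cd14 stood at 281 against 41.3 and 58.5, and Per1, a circadian clock gene, at 135 against 18.6 and 27.1. The basophil gene Fcer1a stood at 3.93 against 14.6 and 14.3. Rpl30, which has similar copies elsewhere in the genome and is uncertain, stood at 1.58 against 54.9 and 35.9. With scaling over all libraries, 3 of these genes were not extreme in it. Nos2 was at 17.8 CPM there and at 39.8 in Mlkl KO Ptpn6 cKO replicate 2. Rpl30 was at 1.72 there and between 1.15 and 1.93 in Ripk3 KO Ptpn6 cKO, and Fcer1a at 4.26 there and 2.12 in Mlkl KO replicate 3. Rpl30 lies on chromosome 15, as does Laptm4b, which differed in the opposite direction. Laptm4b was at 27.7 CPM in this library. Mean Rpl30 and Laptm4b were 79.1 and 0.693 in wild type and 1.41 and 21.5 in Ripk3 KO Ptpn6 cKO. A difference local to chromosome 15 was not tested, so shared reads are not settled as the cause. Of the 27 lists, 6 lay past the 97.5th percentile of 10000 random lists matched on mean expression against both groups, namely gelatinase granule, cell cycle, oxidative burst, ribosomal proteins, glycolysis and hypoxia, and erythroid. Below the 2.5th percentile lay 3, namely NF-kB and inflammatory cytokines, T and NK cell, and basophil and mast cell. Random lists do not carry the spread between libraries. By mean level, cell cycle (4.94) lay inside the range of both groups (4.27 to 4.98 and 4.41 to 4.95), ribosomal proteins (6.83) inside that of Mlkl KO Casp8 cKO Ptpn6 cKO (6.61 to 6.89), and erythroid (5.71) close to the highest library (5.55). On the low side, NF-kB (4.88) and T and NK cell (2.59) lay barely under the lowest library (4.90 and 2.60), and basophil and mast cell (5.03) lay under 5.53.

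Over the 13 comparisons with a single-degree test, 161 list results passed camera's threshold, 87 higher and 74 lower. With a correlation estimated from the data none did, the smallest adjusted p being 0.246. Glycolysis and hypoxia passed most often, higher in 8 comparisons and lower in 3. Azurophil granule, gelatinase granule, cell cycle, basophil and mast cell, and stem and progenitor lists were each higher in 5 and lower in 4. Interferon response was higher in 5 and lower in 3, chemotaxis and adhesion higher in 6 and lower in 2, and B cell higher in 3 and lower in 5. Specific granule and oxidative burst were each higher in 4 and lower in 3, and T and NK cell higher in 2 and lower in 5. ITIM receptors, oxidative phosphorylation, and monocyte and macrophage were each higher in 4 and lower in 2. Immediate early genes were higher in 3 and lower in 3, erythroid higher in 2 and lower in 4, inflammasome and ribosomal proteins higher in 3 and lower in 2, and stroma higher in 2 and lower in 3. The BCL2 family was higher in 3 and lower in 1, and dendritic cell higher in 1 and lower in 3. Eosinophil was lower in 3, necroptosis and TNF receptor signalling lower in 2, NF-kB lower in 1, and megakaryocyte and platelet higher in 1. Plasma cell passed in none by camera, its smallest adjusted p being 0.0569.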

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

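The tests of positions near Ptpn6 and Ap1s1, of the receptor families, of NK cell markers, of intact-Ptpn6 libraries and of the B cell covariate were chosen only after the results were seen. After values were seen, the receptor family and NK marker tests were extended from 1 comparison to 3, the reading of positions near Ptpn6 was changed to open, the receptor family test was repeated in a wider window, and T cell markers were taken out of the NK marker test. The Ap1s1 test first counted Sh2b2 and gave 0.0594, which was read as ruling its explanation out and then as open, before Sh2b2 was left out.

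Sncaip stood out because the effect of Casp8 deletion on it differed with Ripk3 (edgeR adjusted p = 0.00658, log2 difference 6.31). The call was lost in 4 of 9 fits that left out 1 library (log2 difference 4.27 to 6.55) and in the fit of only the libraries compared (log2 difference 6.32, SE 1.09 against 0.83, adjusted p = 0.838), and the level without Ripk3 and Casp8 rested on libraries at 0.5 and 3.65 CPM. The same difference, tested with camera on the fixed lists, passed for 15 of them, all with a preset correlation. Lists whose change with Casp8 deletion was higher in the absence of Ripk3 were interferon response (camera adjusted p = 9.05e-11, 28 of 28 above 0), glycolysis and hypoxia (2.38e-06, 19 of 22), chemotaxis and adhesion (0.000151, 17 of 20), ITIM receptors (0.00206, 21 of 25), oxidative burst (0.00206, 14 of 18), gelatinase granule (0.00706, 12 of 17), monocyte and macrophage (0.00811, 15 of 16), basophil and mast cell (0.0125, 9 of 9), stem and progenitor (0.0281, 10 of 11) and erythroid (0.0302, 13 of 14). Lists whose change was lower were T and NK cell (0.00206, 1 of 13 above 0), ribosomal proteins (0.0027, 1 of 20), cell cycle (0.00341, 0 of 20), oxidative phosphorylation (0.0169, 3 of 20) and B cell (0.0245, 0 of 12). With an estimated correlation none of the lists passed, the adjusted p for interferon response being 0.618. No member gene of these lists passed edgeR's threshold in this comparison, where 1505 genes had an unadjusted p under 0.05 and DESeq2 called 10. Sncaip lies on chromosome 18, as does Wdr7, which was among the 6 smallest p values here. Wdr7 stood at 27.7 ± 2.94 CPM in Mlkl KO Ptpn6 cKO (n = 2). In Ripk3 KO Mlkl KO Casp8 cKO Ptpn6 cKO it stood at 25.8 ± 0.795 (n = 2). Sncaip was highest in these groups. With Casp8 deletion in Mlkl KO Ptpn6 cKO, Wdr7 stood at 19.5 ± 0.474 (n = 2). A difference local to chromosome 18 was not tested, so it cannot be told apart from the deletions.

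Genes called against wild type were crowded near Ptpn6 on chromosome 6 in lines that carry no Ptpn6 deletion, with one-sided Fisher exact p = 1.13e-14 in Ripk3 KO (12 of 196 in the window, 23 of 14807 elsewhere), 1.04e-11 in Mlkl KO (18 and 154) and 1.4e-12 in Ripk3 KO Mlkl KO (18 and 135). No such crowding was seen near the knocked-out genes themselves (Fisher exact p = 1 near Ripk3 in Ripk3 KO and p = 1 near Mlkl in Mlkl KO). In Mlkl KO and Ripk3 KO Mlkl KO, reads shared within the Klr and Clec families are argued against as the whole cause. Without these genes calls stayed crowded there within 10 Mb of Ptpn6 (5 and 6 of 154, Fisher exact p = 0.0238 and 0.00327). In Ripk3 KO 1 of 154 was left (Fisher exact p = 0.212), so shared reads stay open for that line. Within 20 Mb calls were crowded in all 3 lines (7, 13 and 11 of 241, Fisher exact p = 5.09e-08, 1.68e-06 and 1.65e-05). That window was drawn because calls outside the families had been seen just past 10 Mb, so its result cannot decide. Shared reads also stay open in each line for the calls of these families themselves. Fewer natural killer cells are argued against as the whole cause in Ripk3 KO and Ripk3 KO Mlkl KO. The 6 NK cell markers of the fixed list had median log2 changes of 0.07 (-0.49 to 0.79) and 0.08 (-0.65 to 0.55) there. The called genes that fell within 10 Mb had upper quartiles of -2.98 and -3.10, and 1 and 8 called genes rose. In Mlkl KO the markers had a median of -0.90 (-1.47 to -0.11), against an upper quartile of -2.83, and 6 called genes rose. The genes set against the markers were chosen for having fallen, so the comparison cannot decide on the falls in Mlkl KO. The markers Klrb1c and Klrd1 belong to the Klr family themselves. Fewer such cells stay open for the falls in Mlkl KO. Also open are a biological effect of the knockouts, which was not tested, and DNA of another strain on distal chromosome 6. The 16 shared calls there lay between 127.6 and 138.2 Mb, all distal to Ptpn6 at 124.7 Mb and 5 of them over 10 Mb away.

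Ap1s1 and Sh2b2, neighbours on chromosome 5, changed in opposite directions in every library with Ptpn6 deletion. Without these, 3 of 93 genes within 2 Mb of Ap1s1 were called in the averaged comparison (Zfp157, Fam20c and a predicted gene), against 230 of 14909 elsewhere (one-sided Fisher exact p = 0.176). With so few calls this test leaves a transgene or DNA of another strain on chromosome 5 open. A response to the loss of Ptpn6 is open as well, since 0 libraries combined Cre-mediated deletion of another gene with intact Ptpn6.

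The 244 genes called with Ptpn6 deletion in Mlkl KO came with a lower level of B cell markers in the same libraries. With the marker score as a covariate the median size of their log2 changes went from 1.19 to 0.98, a ratio of 0.82, and all 244 kept their sign. The median SE was 0.25 before and after, and 6 of the 244 were still called. A lower share of B cells may account for part of the change, but the score differs between the groups compared, so it cannot be told apart from the deletion itself.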

How the results depend on the processing

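The B cell marker score covariate and all settings of the Ptpn6 gene sets were chosen after the data were seen. Counts of called genes depended on the tool and on single libraries more than on scaling, and DESeq2's size factors in edgeR moved no count by over 1.5 times. DESeq2's tests called 34 genes for Ptpn6 deletion in Ripk3 KO, 763 in Mlkl KO, 4 in Ripk3 Mlkl KO, 662 averaged, 31 for the difference between backgrounds, 94, 780 and 458 against wild type (Ripk3 KO, Mlkl KO, both), 90 and 1 for Casp8 deletion (Mlkl KO, both KO), 10 for its interaction, and 1572, 1 and 3 for loss of Ripk3, of Mlkl, and of Ripk3 with Casp8 deleted. Without a filter Ptpn6 deletion gave 20 in Ripk3 KO, 3 in Ripk3 Mlkl KO, 383 averaged and 1 for the difference, Ripk3 KO against wild type 56, Casp8 deletion 1 in Mlkl KO and 2 for its interaction, and loss of Ripk3 324 and, with Casp8 deleted, 2. Fits of only the libraries compared gave 1 for Ptpn6 deletion in Ripk3 KO, 532 in Mlkl KO, 22 averaged, 1 for the difference, 182, 891 and 833 against wild type, 4 for Casp8 deletion in Mlkl KO, 0 for its interaction (edgeR; 1505 at an unadjusted p under 0.05 in the full fit, 10 by DESeq2), and 1 and 3 for loss of Ripk3 without and with Casp8 deletion, where the 1 was none of the 3 genes of the full fit. The replicate block gave 101 for Ripk3 Mlkl KO against wild type and 431 for loss of Ripk3 in Mlkl KO Ptpn6 cKO. The covariate gave 7 for Ptpn6 deletion in Mlkl KO and 291 for Ripk3 Mlkl KO against wild type. The cause was not tested for any of these.

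Leaving out each library in turn gave 3 to 156 for Ptpn6 deletion in Ripk3 KO, 2 to 191 in Mlkl KO, 1 to 18 in Ripk3 Mlkl KO, 7 to 1037 averaged and 0 to 34 for the difference. Against wild type it gave 23 to 38, 38 to 589 and 19 to 85. Casp8 deletion gave 0 to 1 in both backgrounds and 0 to 2 for the interaction. Loss of Ripk3 gave 2 to 4861, loss of Mlkl 0 to 1, and loss of Ripk3 with Casp8 deleted 1 to 2. The fixed lists gave 147 to 173, with up to 3 of the first 161 turned in direction (without Ripk3 KO Mlkl KO Ptpn6 cKO replicate 1), and the Ptpn6 gene sets 4 to 6, with 1 turned without Ripk3 KO Mlkl KO replicate 3 and 1 without Ripk3 KO Mlkl KO Ptpn6 cKO replicate 3. With the B cell marker score covariate 132 list results passed, 105 of the 161 were kept, and 13 of the 161 turned in direction. The 161 list results fell to 0 by camera with an estimated correlation and to 4 by fry, and the 5 of 6 gene set results to 0 with both. In 4 settings a gene set had under 5 genes and was not run. The 9 lists of the Casp8 cKO Ptpn6 cKO library stayed 9 in number.

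Of 9256 gene results under alternatives, 37 turned direction, none of them from a called gene, and 33 of these came from leaving out a library, for which the range over all libraries left out is given too. With the B cell marker score covariate these were Ccna2 -0.032 (Ripk3 loss in Mlkl KO Ptpn6 cKO), Rrm2 -0.038 (Ripk3 loss in Mlkl KO Ptpn6 cKO), Rpl10a -0.18 (Ripk3 loss in Mlkl KO Ptpn6 cKO), Vpreb3 -0.050 (Mlkl loss in Ripk3 KO Ptpn6 cKO). Ptpn6 deletion in Mlkl KO without Mlkl KO replicate 3 gave Cpa3 -0.038 (range -0.038 to 0.71), Fcer1a -0.002 (range -0.002 to 0.79). Casp8 deletion differs with Ripk3 without Ripk3 KO Mlkl KO Casp8 cKO Ptpn6 cKO replicate 1 gave Car1 -0.28 (range -0.28 to 2.40), Klf1 -0.31 (range -0.31 to 2.16). Casp8 deletion in Ripk3 Mlkl KO Ptpn6 cKO without Ripk3 KO Mlkl KO Casp8 cKO Ptpn6 cKO replicate 1 gave Mefv -0.012 (range -0.012 to 0.67), Ms4a6c -0.17 (range -0.17 to 1.25), Ccr2 -0.16 (range -0.16 to 1.41), Fn1 -0.95 (range -0.95 to 4.08), Ppbp -0.41 (range -0.41 to 5.05), Col1a2 -0.46 (range -0.46 to 6.92), Col1a1 -0.30 (range -0.30 to 4.14), Bglap -4.23 (range -4.23 to 5.47). Mlkl loss in Ripk3 KO Ptpn6 cKO without Ripk3 KO Mlkl KO Ptpn6 cKO replicate 1 gave Ms4a1 -0.068 (range -0.068 to 0.91), Vpreb3 -0.027 (range -0.027 to 0.86). Mlkl loss in Ripk3 KO Ptpn6 cKO without Ripk3 KO Mlkl KO Ptpn6 cKO replicate 3 gave Zfp36 -0.14 (range -0.14 to 0.89). Ptpn6 deletion in Ripk3 Mlkl KO without Ripk3 KO Mlkl KO replicate 2 gave Ifit3 0.006 (range -1.67 to 0.006). Ptpn6 deletion averaged over 3 backgrounds without Ripk3 KO Mlkl KO replicate 3 gave Cd3e 0.046 (range -0.68 to 0.046). Ptpn6 deletion in Ripk3 Mlkl KO without Ripk3 KO Mlkl KO replicate 3 gave C1qa 0.30 (range -2.27 to 0.30), Mrc1 0.18 (range -2.31 to 0.18), Vcam1 0.60 (range -2.22 to 0.60), C1qb 0.12 (range -1.96 to 0.12), H2-Aa 0.039 (range -1.06 to 0.039). Ripk3 Mlkl KO against wild type without Ripk3 KO Mlkl KO replicate 3 gave C1qc -0.98 (range -0.98 to 1.86), C1qb -0.42 (range -0.42 to 1.66), Ear2 0.069 (range -1.37 to 0.069), Prg3 0.43 (range -4.74 to 0.43), Il5ra 0.13 (range -0.41 to 0.13). Mlkl loss in Ripk3 KO Ptpn6 cKO without Ripk3 KO Ptpn6 cKO replicate 1 gave Bglap 4.22 (range -7.87 to 4.22), Col1a2 0.38 (range -7.31 to 0.38), Col1a1 0.69 (range -4.36 to 0.69). Ptpn6 deletion in Ripk3 KO without Ripk3 KO Ptpn6 cKO replicate 1 gave Bglap -6.01 (range -6.01 to 6.13), Pdgfra -2.60 (range -2.60 to 5.24). Ripk3 KO against wild type without wild type replicate 3 gave Spp1 0.13 (range -1.40 to 0.13). For Ripk3 in Mlkl KO against wild type the log2 change was -1.06 with the covariate and -1.87 to -1.35 over the libraries left out, most of them without a call. The cause was not tested.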

Other observations

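The library with conflicting labels had 13256 Ptpn6 counts (582 CPM), 2 Ripk3 counts, 17 Mlkl counts (0.747 CPM) and 700 Casp8 counts (30.7 CPM). Ap1s1 stood at 12.3 and Sh2b2 at 26.7 CPM in it. Its title followed that of the Ripk3 KO Mlkl KO libraries, while its genotype label read Mlkl KO Ptpn6 cKO. The Mlkl KO Ptpn6 cKO libraries had 142 Ripk3 counts in all, Ptpn6 at 188 ± 8.20 and Ap1s1 at 122 ± 49.6 CPM (n = 2). These values argue against that genotype label, and the library was still placed in no group. In the library with conflicting labels Hebp1 stood at 9.97 and Klra17 at 141 CPM.

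The genes called with Ptpn6 deletion in Mlkl KO were also followed with Casp8 deletion in Ripk3 KO Mlkl KO Ptpn6 cKO, a test chosen after the data were seen. None of them passed singly there. Of the 159 higher genes 146 lay higher (median log2 change 0.25, camera adjusted p = 1.49e-19) and of the 82 lower genes 68 lay lower (median -0.22, camera adjusted p = 9.44e-07). With an estimated correlation the adjusted p values were 0.191 and 0.288, and with fry 0.234 and 0.236.

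Other splits of the same 6 libraries into 3 and 3 were counted where both groups had 3. With 10 splits no share under 0.05 can be reached. For Ptpn6 deletion in Ripk3 KO the real split called 3 genes and the highest other 0, for Ripk3 KO against wild type 37 and 0, and for Mlkl KO against wild type 188 and 1, so that 1 of 10 splits gave as many in each. For Mlkl loss in Ripk3 KO Ptpn6 cKO, 10 of 10 splits gave at least the 0 of the real split (edgeR; 482 genes at an unadjusted p under 0.05, 1 by DESeq2). The highest other called 1570, with Ripk3 KO Ptpn6 cKO replicate 1 and Ripk3 KO Mlkl KO Ptpn6 cKO replicates 1 and 2 on the same side, which points to a structure of these samples that does not follow the genotype. B cell markers averaged 6.74, 7.22 and 6.81 log2 units in these libraries. They averaged 5.75 and 6.19 in Ripk3 KO Ptpn6 cKO replicates 2 and 3 and 5.20 in Ripk3 KO Mlkl KO Ptpn6 cKO replicate 3. The cause was not tested.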
